A study of Oryza sativa with 14 samples.

How the data were processed

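RNA-seq read counts of 14 leaf libraries of rice 'Koshihikari' were taken from the deposited tables, with 8 libraries in the file for 2023 and 6 in that for 2024. The largest leaf of vegetative plants was sampled between 09:00 and 10:00, per the labels' protocols, and each leaf is 1 biological replicate. PolyA RNA was made into directional libraries, also per the labels' protocols. The deposited counts are raw reads per locus of the Rice Annotation Project that the authors made against genome build IRGSP 1.0, per the submitters' processing notes, and the label of each table calls them unique exon reads. The aligner, the counter and whether counting used the strand are not given in the sources used here. The values are whole numbers for 37727 genes in each table, and totals per library lay between 8161851 and 23367369. The file for 2024 also holds 2 columns headed as replicate 4 of each treatment, which the labels used here do not describe and which were not used. Gene names and descriptions are those in the deposited tables, with symbols of fixed lists where the tables give none.

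Libraries were grouped by treatment and year, 4 per treatment in 2023 and 3 in 2024. The tests, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, with the exceptions given here. Within each year, counts were filtered with filterByExpr (minimum count 10, minimum total 15), scaled with TMM and compared with the quasi-likelihood F-test of edgeR 4.0.16 with robust dispersion, in R 4.3.3 with the package data.table (version 1.17.8). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The difference between years was tested as the interaction in 1 fit of all 4 groups. Overlap of calls between years was compared with the product of the call counts over the genes tested in both years, and with a one-sided Fisher's exact test. Errors of log2 fold changes are the log2 fold change divided by the square root of its F statistic, and errors of CPM are SD over libraries. CPM values are scaled by TMM.

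The rule named the 10 largest rises and 10 largest falls of each year among called genes that have an informative name or description, a mean of at least 2 CPM and no overlap between the treatments. It also named the 10 largest in each direction by the smaller of their changes over both years, the 6 smallest p of the interaction among genes with an informative name or description, and up to 4 called members of each list (all for nitrogen, phosphate and gibberellin) or the 2 nearest where none was called. Of the genes it named, 1 is not reported here. That the rule uses TMM-scaled CPM was settled after the data were seen. A fold against a group at 0 in all libraries is given as a lower bound from a floor of 3 reads over the group.

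Of the 30 lists, 17 were fixed by locus and 13 by searching the descriptions. The locus lists cover nitrogen uptake and assimilation, phosphate starvation, gibberellin, cytokinin, flowering, the circadian clock, Rubisco and chlorophyll synthesis, leaf senescence, salicylate and pathogenesis-related defence, phytoalexins, jasmonate, iron and zinc, secondary cell wall, potassium and silicon, sucrose and starch, abscisic acid, drought and cold, and meristem and root markers of other tissues. The searched lists cover light-harvesting proteins, photosystem subunits, cytosolic and plastid ribosomal proteins, histones, heat shock proteins, WRKY factors, cellulose synthases, expansins, glutathione S-transferases, peroxidases, chitinases and thaumatins, and terpene synthases. By a rule fixed beforehand 29 loci whose description names another kind of protein were left out, 28 of them from searches. Ribosomal proteins of bacterial type whose description names no plastid or mitochondrion stayed in the cytosolic list. These exclusions were made from descriptions after the tables and some values had been seen. Lists with at least 3 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, log prior count 2), adjusted over the lists of a comparison. Members were also adjusted over the list alone.

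Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors, no filter on low counts, a stricter filter at 5 CPM, an absolute log2 fold change of at least 1, the replicate number as a block, each library left out in turn and all 14 libraries in 1 fit. For lists they were camera with an estimated correlation and fry. Leaving out green manure libraries 1 and 2 of 2023 together and testing lists on the interaction were added after the data were seen. The pipeline was tested on simulated data with 100 genes changed at each of 2 sizes. It recovered 82% of 2-fold and 96% of 4-fold changes at the size and depth of 2023, 67% and 93% at those of 2024, and 43% and 76% for the interaction, with 11, 12 and 5 unchanged genes called. A 1.5-fold rise of a list of 20 genes was recovered in both years, where 0 and 1 of 28 other lists were also called. The simulated genes were drawn independently of each other. The simulation therefore does not test camera on lists whose members are correlated. Pairs of libraries of a group were checked for duplicates, and the lowest chi-square per degree of freedom over 18 pairs was 2.72. That pair was green manure libraries 3 and 4 of 2023, and the other pairs of their group lay between 16.9 and 27. The first principal component of all libraries took 47.9% of the variance and separated the years.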

Results

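Leaf transcripts of the japonica rice cultivar Koshihikari were counted in 14 RNA-seq libraries from plants grown with chemical fertilizer (CF) or with hairy vetch, a legume cover crop, ploughed in as green manure (GM) without chemical fertilizer. In 2023, 4 leaves per treatment were collected 47 days after transplanting, and in 2024, 3 leaves per treatment at 38 days. The vetch had been sown at 30 kg of seed per hectare for 2023 and 60 kg per hectare for 2024, and the chemical fertilizer supplied 56 kg of nitrogen, 176 kg of PO4, 56 kg of K, 90 kg of Mg and 120 kg of SiO2 per hectare. Total counts per library ranged from 8161851 to 11375515 in 2023 and from 13224671 to 23367369 in 2024. Each leaf is a biological replicate per the labels. How many fields or plots stood behind the leaves of a treatment is not stated, so the p-values measure leaf-to-leaf spread and the treatment cannot be told apart from the field. The series is titled for the effect of green manure on yield and grain appearance. The comparisons ask which leaf transcripts differed between the fertilizer regimes in each year, which differed in both years and which effects differed between the years.

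In 2023, leaves grown with green manure carried more transcript of CAB2R (Os01g0600900) and OsGS1;2 (Os03g0223400), and less of ASNASE2 (Os04g0650700) and MAX1D (Os02g0221900), than leaves grown with chemical fertilizer. CAB2R, a chlorophyll a/b-binding protein of the photosystem II antenna, rose from 3380 ± 1100 to 12900 ± 4460 normalised CPM (mean ± SD, n = 4 per treatment), a log2 fold change of 1.93 ± 0.27 (SE). OsGS1;2, a cytosolic glutamine synthetase that assimilates ammonium, rose from 27.5 ± 6.51 to 62.2 ± 12.6 CPM (log2 fold change 1.17 ± 0.17, n = 4). ASNASE2, by its name an asparaginase, went from 1160 ± 225 to 549 ± 87.6 CPM and fell by 1.08 ± 0.15 on the log2 scale (n = 4). MAX1D, a cytochrome P450 related to the strigolactone enzyme MAX1 of Arabidopsis, went from 63.4 ± 19.6 to 17.4 ± 3.49 CPM and fell by 1.86 ± 0.23 (n = 4).

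Of 18577 genes tested in 2023 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 460 were called, 302 higher and 158 lower with green manure. An unadjusted p under 0.05 was seen for 2874. The libraries of the treatments did not overlap for 10% of all tested genes, against 2.86% by chance, and for 448 of the 460 called genes. The largest rises named by the rule belonged to Os03g0280400, with 0 reads in all chemical fertilizer libraries and a level at least 65.5-fold higher with green manure (floor of 3 reads over the group), and to the S-like ribonuclease RNS4 (Os09g0537700, log2 fold change 4.49 ± 0.53, adjusted p = 0.00522). Next came the aspartic peptidase Os12g0583300 (4.37 ± 0.87), Os03g0338000, similar to an alanine-glyoxylate aminotransferase (3.42 ± 0.52). SDI1 (Os03g0165900), a tetratricopeptide-repeat protein that shares its name with a sulfur-deficiency-induced gene of Arabidopsis, rose by 3.34 ± 0.39 (adjusted p = 0.00336). They were followed by the FtsH protease FTSH6 (Os06g0229000, 3.04 ± 0.61), AK-HSDH2 (Os09g0294000, 2.73 ± 0.48), a bifunctional aspartokinase and homoserine dehydrogenase of amino acid synthesis. The microRNA precursor MIR408 (Os01g0322700, 2.61 ± 0.46), the isoflavone reductase-like gene IRL (Os01g0106400, 2.58 ± 0.41) and C3H54 (Os08g0126700, 2.49 ± 0.37) also rose. The largest falls belonged to the DnaJ-domain chaperone gene Os07g0443500 (-3.69 ± 0.73), the mitochondrial carrier gene Os01g0225000 (-2.43 ± 0.40), the protein kinase gene Os02g0615500 (-1.87 ± 0.35), and MAX1D. They were followed by RLCK144 (Os04g0369000, -1.83 ± 0.35), the amino acid carrier AAP11E (Os01g0882800, -1.82 ± 0.43) and OsBBD1 (Os01g0702000, -1.71 ± 0.17, adjusted p = 0.000136). The hydrolase gene Os01g0636400 (-1.67 ± 0.42), the peptidyl-prolyl isomerase OsFKBP62b (Os04g0352400, -1.54 ± 0.26) and the potassium transporter HAK4 (Os08g0466200, -1.50 ± 0.36) also fell. Of these 20 genes, 6 kept their call whichever library was left out and 14 lost it in at least 1 such fit, with adjusted p up to 0.183. The count of called genes was 149, 180 and 150 without chemical fertilizer library 1, 2 or 3. It was 788 without green manure libraries 1 and 2 together, 835 with DESeq2 and 723 in a fit of all 14 libraries.

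Among the gene lists fixed beforehand, the light-harvesting list had the smallest camera p of 2023 with the preset correlation. Of 20 tested members, 7 rose, 0 fell and 13 did not pass the test, with 14 higher when adjusted over the list alone. CAB2R, LHCB2.1 (Os03g0592500, 1.02 ± 0.20, adjusted p = 0.0115), PSAH (Os05g0560000, 1.27 ± 0.25, adjusted p = 0.0302) and CP26 (Os11g0242800, 0.83 ± 0.19, adjusted p = 0.0318) had the smallest adjusted p. PSAH is also described as a reaction center subunit of photosystem I. The median log2 fold change was 0.67. The list passed camera (adjusted p = 9.23e-10), and its adjusted p = 0.696 with an estimated correlation. These genes took 5.67% ± 0.60 of all reads with chemical fertilizer and 8.47% ± 1.49 with green manure (SD, n = 4). The root marker OsLsi1 (Os02g0745100) moved the same way without passing the test (0.89 ± 0.22, adjusted p = 0.0633), though it did when adjusted over its own list alone. Green manure libraries 1 and 2 stood apart on the first principal component of 2023, at 24.6 and 55.4 against 1.2 for each of the others, and without them the list's median was 0.61. With plain library totals in place of TMM the median over all tested genes shifted to -0.19 and that of the light-harvesting list to 0.47. The number of called members lay between 1 and 11 when single libraries were left out.

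Of 29 tested photosystem genes in 2023, 6 were higher, 1 lower and 22 not called (14 higher and 2 lower adjusted over the list alone). The photosystem list overlaps the light-harvesting list, since both hold LHCB2.1, so the 2 lists are not separate evidence. The list had a median of 0.57 and a camera adjusted p = 5.78e-05 (adjusted p = 0.785 with an estimated correlation). PSBO (Os01g0501800), the manganese-stabilising protein of the oxygen-evolving complex, rose from 2660 ± 638 to 5770 ± 1750 CPM (log2 fold change 1.11 ± 0.21, adjusted p = 0.0142, n = 4), and PSAN (Os12g0189400) rose by 1.06 ± 0.21 (adjusted p = 0.0252). The member that fell was PSBS2 (Os04g0690800, -0.77 ± 0.12, adjusted p = 0.00345), a PsbS protein, known for its part in dissipating excess light energy. Of 16 tested genes for Rubisco and chlorophyll synthesis, 2 rose, 0 fell and 14 were not called, with 8 higher and 1 lower adjusted over the list alone. The median was 0.40 and the camera adjusted p = 5.78e-05 (adjusted p = 0.696 with an estimated correlation). The called members were OsPORA (Os04g0678700), a light-dependent protochlorophyllide oxidoreductase (2.02 ± 0.36, adjusted p = 0.0403), and OsCHLH (Os03g0323200), the large subunit of magnesium chelatase (0.60 ± 0.15, adjusted p = 0.044). When single libraries were left out, between 1 and 16 photosystem genes, 0 and 7 Rubisco and chlorophyll genes and 0 and 5 cytosolic ribosomal protein genes were called. The searched list of cytosolic ribosomal proteins was shifted by a small amount. In this list, 203 of 240 tested members had a positive log2 fold change, with a median of 0.18 and a camera adjusted p = 6.24e-07 (adjusted p = 0.785 with an estimated correlation). In that list 1 member was called, Os03g0452300 (0.70 ± 0.16, adjusted p = 0.044), which is described as of bacterial type and so goes against the name of the list. Adjusted over the list alone 0 were called, 32 had an unadjusted p under 0.05 and DESeq2 called 1.

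All 8 tested cytokinin genes had positive log2 fold changes in 2023 (median 0.53, camera adjusted p = 3.9e-05, adjusted p = 0.367 with an estimated correlation). This was the only list of 2023 that the directional fry test called (adjusted p = 0.0287, against 0.226 for the light-harvesting list). Of the cytokinin genes OsRR2 (Os02g0557800), a type-A response regulator induced by cytokinin, rose from 53.2 ± 6.83 to 91.1 ± 9.82 CPM (0.78 ± 0.11, adjusted p = 0.0024, n = 4), and 4 were higher when adjusted over the list alone. All 5 tested terpene synthases had negative values (median -0.36, camera adjusted p = 0.0474, adjusted p = 0.696 with an estimated correlation). Of them TPS24 (Os04g0345400) passed the test (-0.53 ± 0.13, adjusted p = 0.0488), and 2 were lower adjusted over the list alone. Of 14 tested genes for nitrogen uptake and assimilation, OsGS1;2 and OsNADH-GOGAT2 (Os05g0555600, 2.04 ± 0.51, adjusted p = 0.0459), a glutamate synthase, rose, and the nitrate transporter OsNRT2.3 (Os01g0704100, -1.18 ± 0.29, adjusted p = 0.0456) fell. With 2 higher and 5 lower adjusted over the list alone, the nitrogen list had a median of -0.16 and a camera adjusted p = 0.312. Of 9 tested phosphate starvation genes, OsSQD2 (Os07g0100300), a sulfolipid synthase, rose (0.59 ± 0.10, adjusted p = 0.00653), the only call also when adjusted over the list alone (median -0.06, mean 0.10, camera adjusted p = 0.706). OsWRKY45 (Os05g0322900), a transcription factor of salicylate-dependent defence, fell by 0.49 ± 0.11 (adjusted p = 0.0302) as the only call among 8 tested defence genes, with 2 lower adjusted over the list alone (median -0.23, camera adjusted p = 0.217). OsWRKY45 and WRKY64 (Os12g0116700, -1.32 ± 0.30) were the calls among 45 tested WRKY genes. With adjustment over the list alone 1 was higher and 2 lower (median -0.06, camera adjusted p = 0.216). When single libraries were left out, the nitrogen list held between 1 and 2 calls, the cytokinin list between 1 and 3, the phosphate list between 1 and 2, the WRKY list between 0 and 3 and the defence and terpene synthase lists between 0 and 1. OsNADH-GOGAT2, OsNRT2.3 and TPS24 each lost their call in 7 of 8 such fits and OsWRKY45 in 6.

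In 2024, OsPORA and OsCHLI (Os03g0563300) of chlorophyll synthesis were higher with green manure, and ASNASE2, ALN (Os04g0680400) and OsWRKY45 were lower. OsPORA rose from 42.2 ± 9.36 to 224 ± 94.2 CPM (log2 fold change 2.4 ± 0.37, n = 3), and OsCHLI, another magnesium chelatase subunit, from 143 ± 14.6 to 330 ± 94.3 CPM (1.20 ± 0.19, n = 3). ASNASE2 went from 346 ± 97 to 82.2 ± 13.3 CPM and fell by 2.07 ± 0.22 (n = 3), and ALN, the allantoinase of ureide breakdown, went from 69.8 ± 15.7 to 19.3 ± 4.11 CPM and fell by 1.85 ± 0.19 (n = 3). OsWRKY45 went from 48.3 ± 6.18 to 20.1 ± 4.33 CPM and fell by 1.28 ± 0.15 (n = 3).

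The edgeR test called 626 of 19261 genes in 2024, 364 higher and 262 lower with green manure. An unadjusted p under 0.05 was seen for 3292. The treatments did not overlap for 22.6% of tested genes, against 10% by chance, and for all 626 called genes. MIR408 led the rises named by the rule (0.34 ± 0.194 to 11.8 ± 6.46 CPM; 4.96 ± 0.70, adjusted p = 0.0214), ahead of Os06g0108500, similar to a MADS-box factor (4.62 ± 0.77), and the protein kinase CIPK15 (Os11g0113700, 3.49 ± 0.33, adjusted p = 0.000891). Next came the aspartokinase-like gene Os03g0850400 (3.04 ± 0.42), the plasma membrane proton pump AHA6 (Os02g0797300, 2.65 ± 0.24) and Os03g0280400 (2.64 ± 0.29). The beta-tubulin TUB6 (Os05g0413200, 2.58 ± 0.30), the GRAS factor GRAS29 (Os05g0500600, 2.53 ± 0.42), OsPORA and the protein kinase ACTPK2 (Os07g0475900, 2.33 ± 0.32) also rose. The largest falls belonged to WAK82 (Os09g0471500, -2.11 ± 0.26, adjusted p = 0.00226), named as a wall-associated kinase, ASNASE2, the protein kinase gene Os09g0339000 (-2.01 ± 0.20) and PRODH (Os10g0550900, -1.98 ± 0.24), the proline dehydrogenase that starts proline breakdown. Next came MAX1D (-1.91 ± 0.23), the cysteine proteinase gene Os03g0752500 (-1.90 ± 0.36) and ALN. The salicylate hydroxylase S3H (Os04g0581100, -1.81 ± 0.34), OsWRKY62 (Os09g0417800, -1.77 ± 0.27) and WRKY69 (Os08g0386200, -1.76 ± 0.24) also fell. Of these 20 genes, 12 kept their call whichever library was left out and 8 lost it in at least 1 such fit, with adjusted p up to 0.143. The count of called genes was 162, 217 and 290 without chemical fertilizer library 1, 2 or 3, and 1603, 270 and 352 without green manure library 1, 2 or 3. Without chemical fertilizer library 1, 48.8% of the calls were higher with green manure, against 58.1% with all libraries, and 975 genes were called with no filter on low counts.

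Of 20 tested light-harvesting genes, 7 rose in 2024, 0 fell and 13 were not called (17 higher adjusted over the list alone). The list had a median of 0.67 and a camera adjusted p = 6.11e-11 (adjusted p = 0.468 with an estimated correlation). CAB2R rose from 5110 ± 790 to 13900 ± 4300 CPM (1.45 ± 0.22, adjusted p = 0.0101, n = 3), LHCB2.1 by 0.89 ± 0.15 (adjusted p = 0.00968), CP26 by 0.83 ± 0.18 (adjusted p = 0.0304) and LHCA1 (Os06g0320500), of the photosystem I antenna, by 0.81 ± 0.18 (adjusted p = 0.0399). These genes took 5.89% ± 0.55 of all reads with chemical fertilizer and 8.67% ± 1.38 with green manure (SD, n = 3). The markers of other tissues OsLsi1 (0.39 ± 0.13, adjusted p = 0.136) and OsCDKB2;1 (Os08g0512600, 1.58 ± 0.57, adjusted p = 0.174) moved the same way and passed only when adjusted over their own list. With plain library totals the median over all genes shifted to -0.22 and that of the list to 0.43. Of 29 photosystem genes, 8 rose, 0 fell and 21 were not called, with 19 higher adjusted over the list alone. They include LHCB2.1 of the light-harvesting list. The median was 0.68 and the camera adjusted p = 3.11e-07 (adjusted p = 0.468 with an estimated correlation). PSBO (0.92 ± 0.14), PSBQ (Os07g0544800, 1.26 ± 0.22) and PSBW (Os01g0773700, 0.71 ± 0.15) were among them. Of 16 genes for Rubisco and chlorophyll synthesis, 10 rose, 0 fell and 6 were not called, with 12 higher adjusted over the list alone. The median was 0.71 and the camera adjusted p = 6.16e-09 (adjusted p = 0.468 with an estimated correlation). The smallest adjusted p belonged to OsCHLD (Os03g0811100, 0.77 ± 0.13, adjusted p = 0.00928), OsHEMA1 (Os10g0502400, 0.95 ± 0.15, adjusted p = 0.01), OsCHLI (adjusted p = 0.0156) and the transcription factor OsGLK1 (Os06g0348800, 0.64 ± 0.12, adjusted p = 0.0175). Rubisco small-subunit genes and the CAB genes have near-identical copies, and a count of unique reads could leave out reads shared between copies. When single libraries were left out, the called members numbered between 1 and 17 for the light-harvesting list, 0 and 19 for the photosystem list and 1 and 12 for the Rubisco and chlorophyll list.

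**Figure D1:**
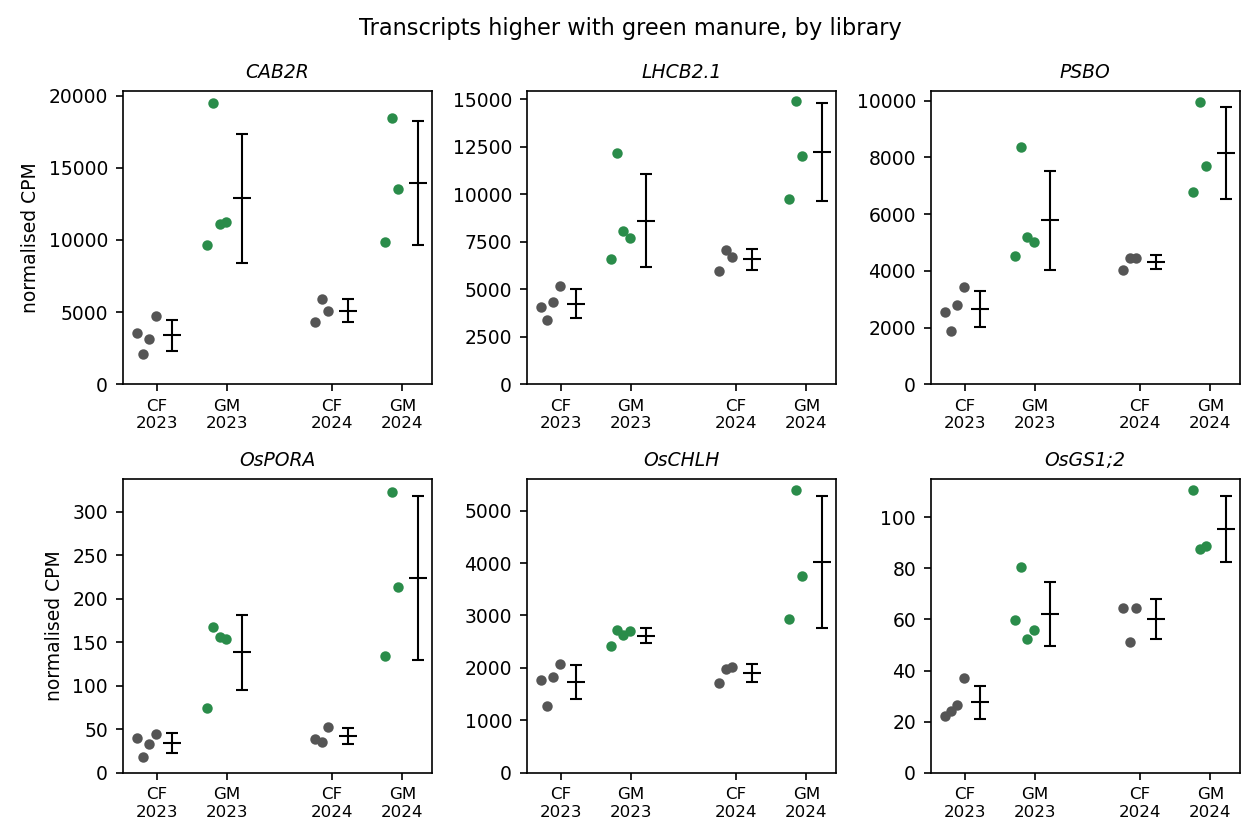
Normalised CPM (vertical axes, each from 0) of 6 transcripts in every library of the 4 groups, chemical fertilizer (CF, grey) and green manure (GM, green) in 2023 (n = 4 each) and 2024 (n = 3 each), with the mean and SD of each group as a bar beside the points. The mean of CAB2R was 3380 and 12900 CPM with chemical fertilizer and green manure in 2023 and 5110 and 13900 CPM in 2024, and PSBO, OsPORA, OsCHLH, LHCB2.1 and OsGS1;2 passed the test in both years.

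The searched list of cytosolic ribosomal proteins had positive values for 207 of 239 tested members in 2024 (median 0.23, camera adjusted p = 5.27e-09, adjusted p = 0.634 with an estimated correlation). Os01g0678600 (0.59 ± 0.12, adjusted p = 0.0252), described only as of the S20 family, and Os03g0452300 (0.42 ± 0.10, adjusted p = 0.0446), of bacterial type, rose, so that no called member is described as cytosolic. Adjusted over the list alone 0 were called, 39 had an unadjusted p under 0.05 and DESeq2 called 4. Of 50 plastid ribosomal protein genes, 3 rose, also when adjusted over the list alone: UCIP11 (Os03g0856500, 1.62 ± 0.28, adjusted p = 0.0343), RPL21 (Os02g0259600, 0.74 ± 0.15) and Os02g0189000 (0.52 ± 0.11). The list had a median of 0.13 and a camera adjusted p = 0.0226 (adjusted p = 0.634 with an estimated correlation). The ferritin genes OsFER1 (Os11g0106700, 0.89 ± 0.17, adjusted p = 0.0216) and OsFER2 (Os12g0106000, 0.83 ± 0.18, adjusted p = 0.0376), near-identical copies that encode the iron store of plastids, rose among 5 tested iron and zinc genes (3 higher adjusted over the list alone). The median was 0.81 and the camera adjusted p = 0.00092 (adjusted p = 0.468 with an estimated correlation). Between 0 and 2 of them, and between 0 and 3 plastid and 0 and 2 cytosolic ribosomal protein genes, were called when single libraries were left out.

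In 2024 all 8 tested salicylate and pathogenesis-related genes had negative values (median -0.88, camera adjusted p = 1.61e-05, adjusted p = 0.249 with an estimated correlation). The directional fry test called the list (adjusted p = 0.00679). Of the 8 genes 4 fell, also when adjusted over the list alone. They were OsWRKY45 (adjusted p = 0.00297), OsWRKY62 (adjusted p = 0.00583), OsWRKY76 (Os09g0417600, -1.50 ± 0.20, adjusted p = 0.0052) and NH1 (Os01g0194300, -0.90 ± 0.20, adjusted p = 0.0337), the rice counterpart of the salicylate co-regulator NPR1. OsWRKY62 and OsWRKY76 are known as repressors of defence, so that the members that fell act in opposite ways. Of 44 tested WRKY genes, 6 fell and 0 rose, with 8 lower adjusted over the list alone. The median was -0.34 and the camera adjusted p = 1.08e-05 (adjusted p = 0.468 with an estimated correlation). The list shares OsWRKY45, OsWRKY62 and OsWRKY76 with the defence list. Of 5 tested terpene synthases, TPS24 (-0.98 ± 0.12, adjusted p = 0.00241), TPS29 (Os08g0139700, -0.70 ± 0.12, adjusted p = 0.00946) and OsTPS10 (Os03g0348200, -0.47 ± 0.11, adjusted p = 0.0411) fell. Adjusted over the list alone, 4 were lower. The terpene synthase list had a median of -0.70 and a camera adjusted p = 0.00016 (adjusted p = 0.468 with an estimated correlation). The directional fry test called it as well (adjusted p = 0.0486). The jasmonate list had a median of -0.51 (camera adjusted p = 0.0178, adjusted p = 0.633 with an estimated correlation). The JAZ repressor OsTIFY10b (Os07g0615200, -0.49 ± 0.12, adjusted p = 0.0493) was called of 8 tested, with 2 lower adjusted over the list alone. Phytoalexin genes had a median of -0.48 over 4 tested (camera adjusted p = 0.042, adjusted p = 0.468 with an estimated correlation). Leaf senescence genes had a median of -0.17 over 9 tested (camera adjusted p = 0.0491, adjusted p = 0.468 with an estimated correlation). In these last 2 lists edgeR and DESeq2 called 0 members. Adjusted over the list alone 1 phytoalexin and 0 senescence genes were lower, and 1 and 3 had an unadjusted p under 0.05. When single libraries were left out, between 3 and 4 defence, 5 and 14 WRKY, 1 and 4 terpene synthase and 0 and 4 jasmonate genes were called. NH1, OsTPS10 and OsTIFY10b each lost their call in 5 of 6 such fits. OsCPS2 (Os02g0571100, -0.33 ± 0.10, adjusted p = 0.0985), CYP99A3 (Os04g0178400, -0.54 ± 0.27, adjusted p = 0.353), OsRCCR1 (Os10g0389200, -0.78 ± 0.28, adjusted p = 0.163) and SGR (Os09g0532000, -0.45 ± 0.17, adjusted p = 0.215) came nearest.

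Of 14 tested nitrogen genes, OsGS1;2 rose in 2024 (0.67 ± 0.12, adjusted p = 0.0137). The nitrate reductase OsNR1 (Os08g0468100, -0.84 ± 0.13, adjusted p = 0.00527), the ammonium transporter OsAMT1;1 (Os04g0509600, -0.54 ± 0.09, adjusted p = 0.00797) and a further cytosolic glutamine synthetase, OsGS1;1 (Os02g0735200, -0.41 ± 0.10, adjusted p = 0.0413), fell. With 2 higher and 7 lower adjusted over the list alone, the nitrogen list had a median of -0.37 and a camera adjusted p = 0.0268 (adjusted p = 0.468 with an estimated correlation). Of 9 phosphate starvation genes, OsSQD2 rose (0.87 ± 0.15, adjusted p = 0.0151). The phosphate transporters OsPT1 (Os03g0150600, -1.17 ± 0.16, adjusted p = 0.00297) and OsPT4 (Os04g0186400, -0.81 ± 0.10, adjusted p = 0.00241), the phosphate exporter OsPHO1;2 (Os02g0809800, -0.51 ± 0.09, adjusted p = 0.0137) and the SPX-domain sensor OsSPX6 (Os07g0614700, -0.50 ± 0.12, adjusted p = 0.0384) fell. Adjusted over the list alone, 2 phosphate genes were higher and 4 lower (median -0.50, camera adjusted p = 0.145). When single libraries were left out, between 2 and 5 nitrogen and 2 and 6 phosphate genes were called, and OsGS1;1 lost its call in 5 and OsSPX6 in 4 of 6 such fits. OsPHO1;2 is known to have antisense transcripts, and the use of strand in counting is not given in the sources used here.

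**Figure D2:**
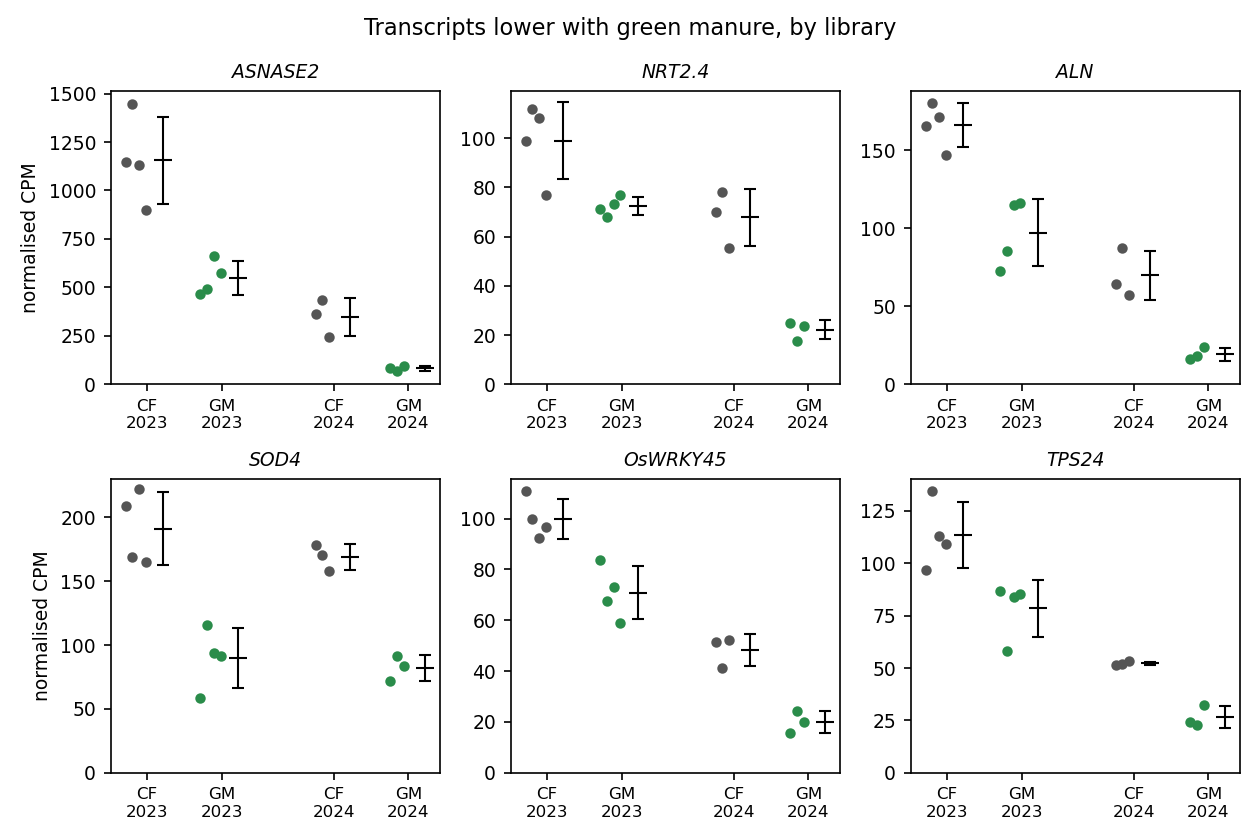
Normalised CPM (vertical axes, each from 0) of 6 transcripts in every library, chemical fertilizer (CF, grey) and green manure (GM, green) in 2023 (n = 4 each) and 2024 (n = 3 each), with the mean and SD of each group as a bar beside the points. The mean of ASNASE2 was 1160 and 549 CPM with chemical fertilizer and green manure in 2023 and 346 and 82.2 CPM in 2024, and all 6 transcripts passed the test in both years.

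Many of these effects recurred. Of 18227 genes tested in both years, 112 were called higher with green manure in both (5.73 expected for independent lists; one-sided Fisher's exact test, p = 3.52e-118). Lower in both were 54 (2.19 expected, p = 2.37e-61 by the same exact test), and 0 were called in opposite directions. The exact test treats genes as independent, and genes of one pathway can move together, so these p-values can overstate the strength of the overlap. The years share no library, but the fields behind the leaves are not stated. Of the calls of 2023 that were tested in 2024, 417 of 453 (92.1%) had the same sign, as had 584 of 609 (95.9%) of the calls of 2024 in 2023. Of all genes tested in both years, 61.9% had the same sign. Across all genes, which are not independent replicates, the log2 fold changes of the years correlated with Spearman's rho 0.38 and Pearson's r 0.50. DESeq2 called 358 genes in both years. The count was 65, 81 and 67 without chemical fertilizer library 1, 2 or 3 of 2023. It was 64 and 88 without chemical fertilizer library 1 or 2 of 2024, 106 without green manure library 2 of 2024, and 41 with an absolute log2 fold change of at least 1 required in each year.

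MIR408, TUB6, OsPORA and AK-HSDH2 were among the genes with the largest rises in both years. AK-HSDH2 rose from 26.2 ± 15.8 to 174 ± 64.3 CPM in 2023 (n = 4; adjusted p = 0.0446) and from 158 ± 21.4 to 634 ± 164 CPM in 2024 (2.00 ± 0.19, adjusted p = 0.00161, n = 3). TUB6 rose by 2.43 ± 0.38 in 2023 and 2.58 ± 0.30 in 2024. Os03g0764600, described as a member of the NIGT1 and HHO family of nitrate-responsive repressors, rose from 19.2 ± 3.8 to 55 ± 7.66 CPM in 2023 (1.52 ± 0.14, adjusted p = 0.000136) and from 78.5 ± 15.5 to 217 ± 29.5 CPM in 2024 (1.47 ± 0.15, adjusted p = 0.00166). The other rises named by the rule were Os03g0280400, Os03g0850400 (1.78 ± 0.36 and 3.04 ± 0.42 in 2023 and 2024), the rhodanese-domain gene STR1 (Os02g0596000, 1.78 ± 0.34 and 1.94 ± 0.25), FTSH6 (3.04 ± 0.61 and 1.65 ± 0.25) and UCIP11 (1.53 ± 0.25 and 1.62 ± 0.28). SOD4 (Os08g0561700), a superoxide dismutase with a Cu/Zn domain, went from 191 ± 28.4 to 90.1 ± 23.5 CPM in 2023 (-1.09 ± 0.18, adjusted p = 0.00956, n = 4) and from 169 ± 10.4 to 82.3 ± 10.2 CPM in 2024 (-1.04 ± 0.11, adjusted p = 0.000891, n = 3). The other falls were MAX1D (-1.86 and -1.91), Os11g0227800 of the NB-ARC resistance protein family (-1.37 ± 0.24 and -1.71 ± 0.20), and the kinase genes Os09g0339000 (-1.19 ± 0.15 and -2.01 ± 0.20) and Os06g0581500 (-1.05 ± 0.16 and -1.46 ± 0.22). AAD (Os09g0327300, -1.12 ± 0.18 and -1.62 ± 0.23), ASNASE2 (-1.08 and -2.07), the wall-associated kinases WAK85 (Os09g0471800, -1.08 ± 0.21 and -1.58 ± 0.29) and WAK82 (-1.06 ± 0.18 and -2.11 ± 0.26) and the protein phosphatase gene Os03g0104100 (-0.99 ± 0.18 and -1.06 ± 0.19) also fell. Of these 20 genes, 8 kept their call of 2023 and 10 their call of 2024 whichever library of the year was left out, the others reaching adjusted p up to 0.148 and 0.143. In 2023 the call of MIR408 was lost in 7, and those of OsPORA and AK-HSDH2 in 6, of the 8 fits without a library. In 2024 that of MIR408 was lost in 3 and that of OsPORA in 4 of the 6 fits.

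**Figure D3:**
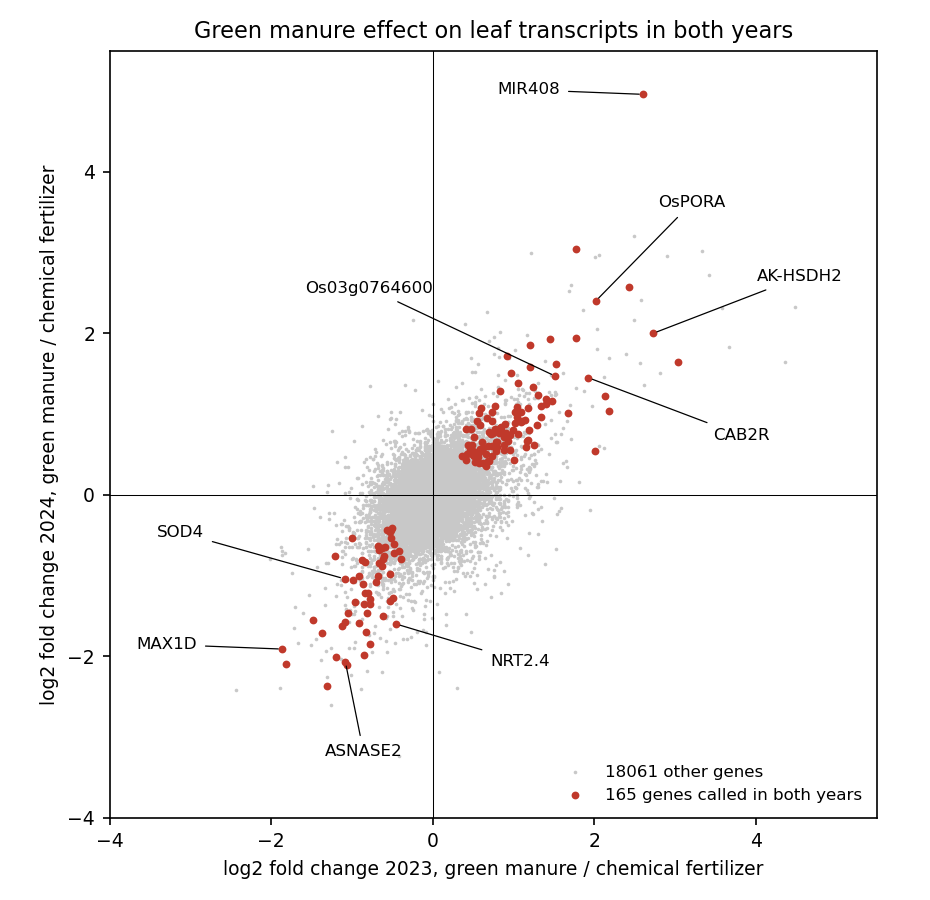
Log2 fold change of each gene, green manure over chemical fertilizer, in 2023 (horizontal axis; n = 4 per treatment) and 2024 (vertical axis; n = 3 per treatment), with 165 genes called in both years in red among 18226 drawn. Os03g0280400, with 0 reads in all chemical fertilizer libraries of 2023, is not drawn. All red points lie in the quadrants where the signs of the years are alike, MIR408 at 2.61 and 4.96, MAX1D at -1.86 and -1.91.

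Few effects differed between the years by the test of the difference itself. PPR6 (Os05g0574800), by its name a pentatricopeptide-repeat gene, fell in 2023 (37.3 ± 1.26 to 17.6 ± 1.41 CPM; -1.08 ± 0.10, n = 4) and was at 7.65 ± 1.72 and 9.63 ± 1.85 CPM in 2024 (0.35 ± 0.19, adjusted p = 0.388, n = 3). The difference was 1.43 ± 0.21 (adjusted p = 0.0208). SWEET2B (Os01g0700100), a sugar transporter of the SWEET family, had 57 ± 4.01 and 68.8 ± 5.4 CPM in 2023 (0.27 ± 0.10, adjusted p = 0.172, n = 4) and fell from 161 ± 27.8 to 94.9 ± 8.42 CPM in 2024 (-0.76 ± 0.12, adjusted p = 0.00785, n = 3). The difference was -1.03 ± 0.16 (adjusted p = 0.0254). These were the 2 calls of edgeR's quasi-likelihood test among 19805 genes. An unadjusted p under 0.05 was seen for 1252, and DESeq2 called 17. Next came NRT2.4 (Os01g0547600), a high-affinity nitrate transporter that fell in both years (-0.45 ± 0.11 in 2023 and -1.60 ± 0.16 in 2024; difference -1.15 ± 0.20, adjusted p = 0.0752). Among genes with an informative name or description it was followed by NAC22 (Os03g0133000, difference -1.51 ± 0.28, adjusted p = 0.118), the non-coding transcript Os02g0597950 (-1.18 ± 0.22, adjusted p = 0.124) and ALDH18B2 (Os01g0848200, 1.11 ± 0.23, adjusted p = 0.247). The difference of PPR6 lost its call in 6 and that of SWEET2B in 7 of the 14 fits without a library, with adjusted p up to 0.0938 and 0.143. The count was 0 without any of chemical fertilizer libraries 1, 2 and 3 of 2023, green manure library 4 of 2023, chemical fertilizer library 2 of 2024 or green manure library 3 of 2024. It was 1 without green manure library 2 of 2024, 4 without chemical fertilizer library 3 of 2024 and 13 without green manure library 1 of 2024.

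The lists with an effect that differed between years by camera were the defence list (median difference, 2024 minus 2023, -0.65, adjusted p = 1.63e-05), WRKY genes (-0.24, adjusted p = 0.00308) and clock genes (0.20, adjusted p = 0.00673). They became adjusted p = 0.0568, adjusted p = 0.388 and adjusted p = 0.335 with an estimated correlation. The test also called Rubisco and chlorophyll synthesis (0.40, adjusted p = 0.0214), phosphate starvation (-0.32, adjusted p = 0.0316), cytokinin (-0.36, adjusted p = 0.0399) and jasmonate (-0.32, adjusted p = 0.0399). These became adjusted p = 0.616, adjusted p = 0.335, adjusted p = 0.414 and adjusted p = 0.414 with an estimated correlation. The light-harvesting and photosystem lists had median differences of 0.03 (camera adjusted p = 0.759) and 0.06 (camera adjusted p = 0.372). In none of the 30 lists was a member called for the difference by edgeR, 50 list entries had an unadjusted p under 0.05 and DESeq2 called 1. Adjusted over the list alone, 3 defence, 4 WRKY and 3 phosphate genes were lower. By the same measure 0 clock, cytokinin, jasmonate or Rubisco and chlorophyll genes differed.

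The gibberellin list, which includes genes of the GA20ox family named in the series title, had 13 of its 17 members tested in each year. In either year 0 of the 13 were called by edgeR at an adjusted p under 0.05. An unadjusted p under 0.05 was seen for 4, and DESeq2 called 2, in each year. Members left untested, which may include GA20ox genes, are not covered by these counts, and single GA20ox genes are not reported here. OsGA2ox6 (Os04g0522500, -0.93 ± 0.24, adjusted p = 0.0539) and OsKS1 (Os04g0611800, -0.46 ± 0.14, adjusted p = 0.105) came nearest in 2023, and OsGA2ox4 (Os05g0514600, -1.21 ± 0.32, adjusted p = 0.09) and the receptor GID1 (Os05g0407500, -0.28 ± 0.09, adjusted p = 0.136) in 2024. In the gibberellin list 2 genes were lower in 2023 and 0 in 2024 when adjusted over the list alone (medians -0.05 and -0.11, camera adjusted p = 0.83 and 0.51). Flowering genes had medians of -0.13 and 0.15 (camera adjusted p = 0.26 and 0.726). OsMADS14 (Os03g0752800, -1.16 ± 0.57) was among the nearest in 2023, as were OsPRR37 (Os07g0695100, 0.25 ± 0.10) and Ghd7 (Os07g0261200, 0.61 ± 0.27) in 2024. The 12 clock genes had medians of -0.12 and 0.12 (camera adjusted p = 0.216 and 0.154). OsFKF1 (Os11g0547000, -0.30 ± 0.11) and OsZTL2 (Os06g0694000, -0.22 ± 0.11) came nearest in 2023, and OsPRR73 (Os03g0284100, 0.29 ± 0.12) and OsLHY (Os08g0157600, 0.21 ± 0.11) in 2024. The sucrose and starch list held no call (medians 0.11 and 0.02, camera adjusted p = 0.881 and 0.89), with OsAGPS2 (Os08g0345800) at 0.29 ± 0.12 and 0.43 ± 0.13 and OsSPS1 (Os01g0919400) at -0.19 ± 0.11 and -0.25 ± 0.11. Nor did the secondary cell wall list (medians 0.03 and 0.17, camera adjusted p = 0.895 and 0.866), with OsCesA4 (Os01g0750300, 0.13 ± 0.51) and Os4CL3 (Os02g0177600, 0.05 ± 0.19) nearest in 2023 and OsPAL2 (Os02g0626400, -0.26 ± 0.16) and OsCesA7 (Os10g0467800, 0.35 ± 0.53) in 2024. The abscisic acid, drought and cold list held 0 calls (medians -0.02 and -0.19, camera adjusted p = 0.881 and 0.34), with OsbZIP23 (Os02g0766700) at -0.15 ± 0.11 and -0.13 ± 0.11, SalT (Os01g0348900) at 1.59 ± 0.74 and -0.16 ± 0.21 and OsDREB1A (Os09g0522200) at -0.07 ± 0.42 and -0.53 ± 0.66. When adjusted over the list alone, 1 sucrose and starch gene was higher in 2024, and 0 flowering, clock, secondary wall or abscisic acid genes were called in either year. Lists without a call by edgeR numbered 13 in 2023 and 12 in 2024, with 18 and 24 members at an unadjusted p under 0.05 and 5 and 3 called by DESeq2.

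Other lists held isolated calls. The cellulose synthase-like gene CSLE6 (Os09g0478300) rose in both years (1.68 ± 0.22, adjusted p = 0.00621, and 1.01 ± 0.13, adjusted p = 0.00297), and CSLH1 (Os10g0341700, 0.73 ± 0.11) and CSLE1 (Os09g0478100, 0.88 ± 0.15) in 2023. Of 21 and 24 tested members 4 and 1 were higher adjusted over the list alone (medians 0.00 in each year, camera adjusted p = 0.441 and 0.894). GSTF2 (Os01g0764000) fell in both years (-0.50 ± 0.09 and -0.41 ± 0.09), and GSTL2 (Os03g0283100, 0.43 ± 0.11) rose in 2023, among 21 and 23 tested glutathione S-transferases. Of these 2 were higher and 1 lower in 2023 and 1 lower in 2024 when adjusted over the list alone (medians 0.12 and -0.02, camera adjusted p = 0.706 and 0.641). The peroxidases PRX20 (Os01g0962700, 0.86 ± 0.20) and Os03g0762300 (0.72 ± 0.18) rose among 28 tested in 2023. In 2024, 0 of 35 were called by edgeR or DESeq2 and 4 had an unadjusted p under 0.05, with PRX16 (Os01g0327400, -0.69 ± 0.23) and prx75 (Os05g0499400, -0.29 ± 0.11) nearest. Called when adjusted over the list alone were 2 and 0 (medians 0.10 and -0.01, camera adjusted p = 0.494 and 0.894). The chitinase CHT6 (Os02g0605900, 0.94 ± 0.20) rose in 2023 and C10728 (Os01g0660200, -0.79 ± 0.17) fell in 2024 among 23 tested chitinases and thaumatins. In 2023, 1 was higher adjusted over the list alone, and in 2024, 1 was higher and 2 lower (medians 0.09 and -0.16, camera adjusted p = 0.494 and 0.34). HSP17.9B (Os01g0135900, -0.57 ± 0.09) fell in 2024 and Os07g0443500 in 2023 among 86 and 87 tested heat shock genes. Of these, 0 and 1 were called adjusted over the list alone, 17 and 16 had an unadjusted p under 0.05 and DESeq2 called 2 and 4 (medians -0.05 and 0.00, camera adjusted p = 0.216 and 0.726). The histone gene Os07g0549900 (0.74 ± 0.12) rose among 36 tested in 2024, also adjusted over the list alone. In 2023, 0 of 30 histone genes were called by edgeR, over the list alone or by DESeq2, and 5 had an unadjusted p under 0.05, with Os07g0545300 (0.41 ± 0.14) and Os03g0279200 (-0.28 ± 0.12) nearest (medians -0.06 and -0.17, camera adjusted p = 0.83 and 0.0554). The potassium transporter OsHAK5 (Os01g0930400, -0.93 ± 0.23) fell among 4 potassium and silicon genes in 2023, where 1 was higher and 1 lower adjusted over the list alone. In 2024 edgeR and DESeq2 called 0, 2 had an unadjusted p under 0.05 and 1 was higher adjusted over the list alone (medians -0.19 and 0.08, camera adjusted p = 0.854 and 0.866). OsLsi1 (0.39 ± 0.13) and OsHAK1 (Os04g0401700, -0.74 ± 0.32) came nearest in 2024. Expansins had 10 tested members, 0 calls by edgeR or DESeq2 and 2 and 3 at an unadjusted p under 0.05. Lower when adjusted over the list alone were 0 and 1 (medians -0.17 and -0.27, camera adjusted p = 0.941 and 0.79). The nearest were EXPR1 (Os07g0496250, -0.77 ± 0.26) and EXPL1 (Os03g0132200, 0.56 ± 0.22) in 2023 and EXPB2 (Os10g0555700, -0.61 ± 0.18) and EXPB7 (Os03g0102700, -0.58 ± 0.19) in 2024.

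Of the remaining lists in the year not yet described, OsRR2 rose in 2024 (0.54 ± 0.10, adjusted p = 0.016) as the only call among 8 cytokinin genes, also when adjusted over the list alone (median 0.11, camera adjusted p = 0.202). UCIP11 was the only call among 50 plastid ribosomal protein genes in 2023, also adjusted over the list alone (median 0.11, camera adjusted p = 0.26). OsNAS3 (Os07g0689600), a nicotianamine synthase of iron transport, had a log2 fold change of 1.44 ± 0.29 (adjusted p = 0.0502) in 2023. In that year 0 of 5 iron and zinc genes were called by edgeR, 1 by DESeq2, 1 at an unadjusted p under 0.05 and 1 when adjusted over the list alone (median 0.37, camera adjusted p = 0.216). In 2023 the jasmonate, phytoalexin and leaf senescence lists held 0 calls by edgeR and 1, 0 and 0 by DESeq2. At an unadjusted p under 0.05 were 1, 0 and 1 members, and adjusted over the list alone 1, 0 and 0 (medians -0.11, -0.07 and 0.02, camera adjusted p = 0.881, 0.941 and 0.911). The nearest were OsAOC (Os03g0438100, 0.35 ± 0.10) and OsTIFY10b (-0.17 ± 0.12), OsCPS4 (Os04g0178300, 0.38 ± 0.47) and OsCPS2 (-0.07 ± 0.11), and OsRCCR1 (-0.49 ± 0.23) and NOL (Os03g0654600, 0.33 ± 0.19). Markers of other tissues were few. OsLsi1, a silicon channel known from roots, had 14.1 ± 4.1 and 26 ± 6.4 CPM in 2023 (0.89 ± 0.22, adjusted p = 0.0633) and 18.6 ± 2.33 and 24.4 ± 3.6 CPM in 2024 (0.39 ± 0.13, adjusted p = 0.136). The dividing-cell kinase OsCDKB2;1 had 0.463 ± 0.271 and 1.48 ± 0.885 CPM in 2024 (1.58 ± 0.57, adjusted p = 0.174). These 1 and 2 tested markers were higher when adjusted over the list alone, and DESeq2 called 1 and 0. Median, mean and test differed in sign in 8 of the 29 lists tested in 2023 and 5 in 2024, of which 0 were called by camera.

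**Figure D4:**
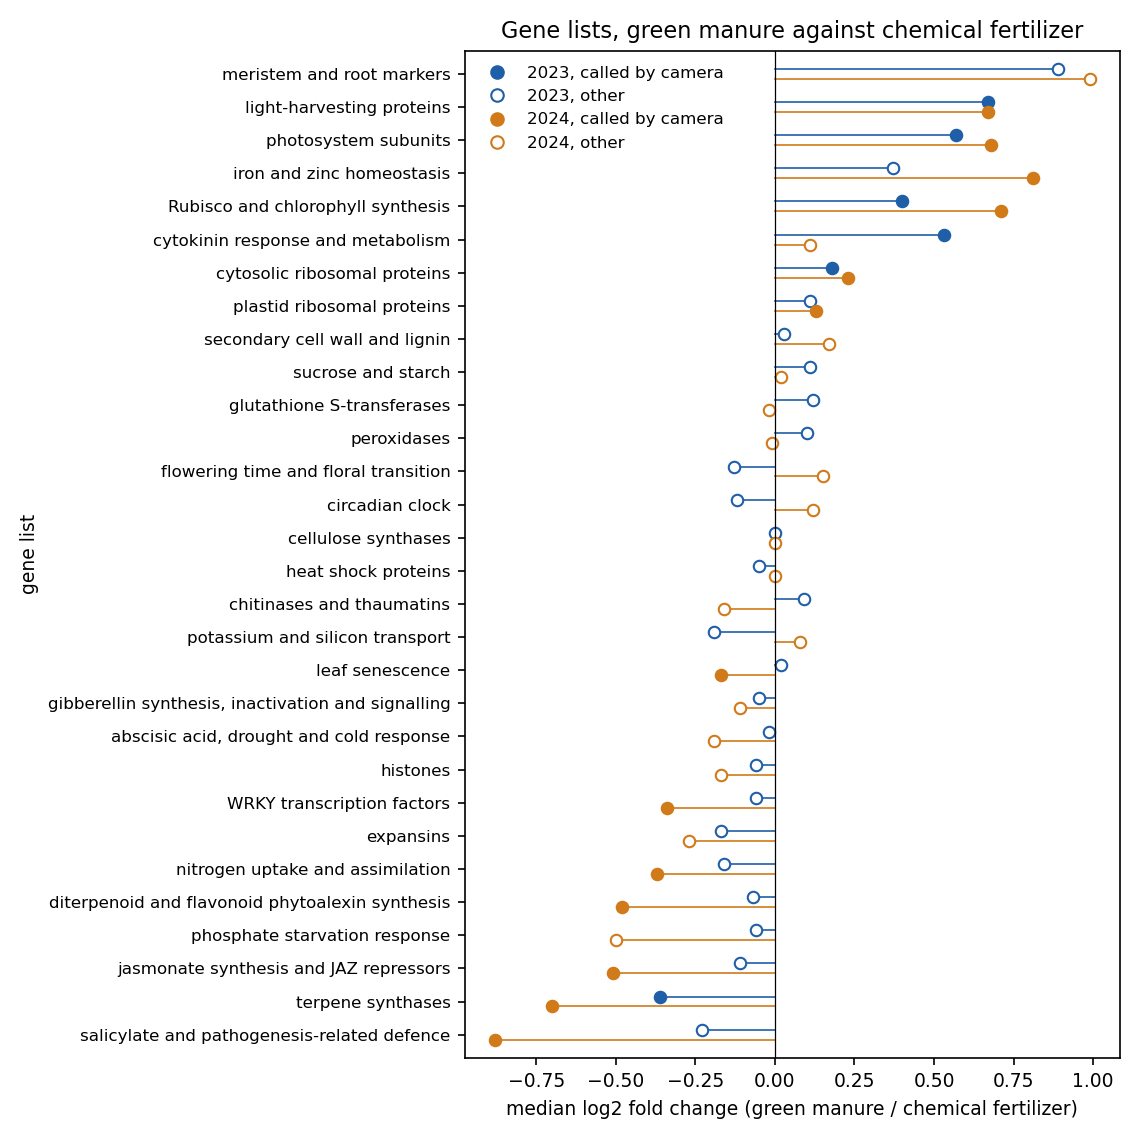
Median log2 fold change of the tested members of each of the 30 lists, green manure over chemical fertilizer, in 2023 (blue) and 2024 (orange). Filled circles mark lists called by camera with its preset correlation, 6 in 2023 and 13 in 2024, of which 0 remained with an estimated correlation. The light-harvesting list lies at 0.67 in each year and the defence list at -0.23 in 2023 and -0.88 in 2024.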

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

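The list tests of the difference between years were chosen only after results were seen, as were superoxide dismutase FSD1.1 (Os06g0115400) and plastocyanin PC (Os06g0101600) among the genes below. Groups of 4 libraries, all of 2023, were searched for a library far from the other 3. Chance alone gives about 1 in 20 such groups, and 21 of 328 gene groups, 4 of 58 list groups and 0 of 8 measures of whole libraries had one.

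In chemical fertilizer library 4, FTSH6 stood at 2.09 CPM (0.529 to 0.694 in the others), AK-HSDH2 at 49.5 (15 to 20.6) and MIR408 at 11.5 (2.37 to 3.6), each towards the green manure values. In the same library WAK85 stood at 11.8 CPM (16.4 to 17.3), HSP17.9B at 76.7 (88.1 to 89.9) and the sucrose and starch list at a mean log2 CPM of 7.26 (7.3 to 7.31). In chemical fertilizer library 2, RLCK144 stood at 9.95 CPM (5.01 to 5.57), WRKY69 at 7.31 (11 to 11.2) and the potassium transporter OsHAK1 (Os04g0401700) at 24.4 (10.5 to 10.9). In that library the expansin EXPB2 stood at 3.81 CPM (7.29 to 7.73) and the heat shock list at a mean log2 CPM of 4.5 (4.56 to 4.57). Library 4 was the far library in 6 and library 2 in 5 of these cases.

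In green manure library 2, CAB2R stood at 19500 CPM (9680 to 11300 in the others), PC at 3970 (2600 to 2740), FSD1.1 at 73 (51.3 to 52.7) and STR1 at 28.4 (12.8 to 15.2). In the same library Os06g0108500 stood at 6.22 CPM (0.116 to 0.729), TPS24 at 58 (83.8 to 86.7) and OsTIFY10b at 92.3 (126 to 132). In green manure library 1, OsPORA stood at 74.9 CPM (154 to 168), OsHAK1 at 20.9 (5.31 to 5.93) and AHA6 at 0.62 (0 to 0.104). In that library the Rubisco and chlorophyll list had a mean log2 CPM of 9.07 (9.61 to 9.7) and the potassium and silicon list of 4.39 (3.93 to 4). In green manure library 4, Os09g0339000 stood at 23 CPM (17.3 to 17.6) and Os03g0752500 at 3.14 (1.51 to 1.77).

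The effect of green manure differed between years, 2024 minus 2023, for PPR6 (1.43) and SWEET2B (-1.03) by edgeR's interaction test. Of 100 splits of the libraries, drawn at random with the real one included, 5 gave as many genes as the real 2. The highest others gave 136 and 41 genes, and both kept the real groups of 2024 while mixing those of 2023. This can turn the treatment effect of 2024 into a difference between years, though other drawn splits of that kind gave 0 genes. These splits therefore do not exclude chance for this count, nor do they measure it. By the list test the median effect differed for WRKY genes (-0.24), clock genes (0.2), Rubisco and chlorophyll synthesis (0.4), phosphate starvation (-0.32), cytokinin (-0.36) and jasmonate (-0.32), and none of these 6 calls was kept with an estimated correlation.

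The effect of green manure on all 8 defence genes was lower in 2024 than in 2023, with a median difference of -0.65, but edgeR and DESeq2 called 0 of them for the difference and 4 had an unadjusted p under 0.05. The list call was lost with an estimated correlation (adjusted p = 0.0568) and kept by the directional fry test (adjusted p = 0.0252). Without each of the 6 libraries of 2024 in turn the median difference was -0.66, -0.71 and -0.69 (chemical fertilizer libraries 1, 2 and 3) and -0.73, -0.49 and -0.7 (green manure libraries 1, 2 and 3), which argues against a single library of 2024 as the cause. Days after transplanting, seed rate of the vetch and season all differed between the years, and none of these was tested.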

How the results depend on the processing

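Leaving out green manure libraries 1 and 2 of 2023 together was chosen after results were seen. With each library left out in turn, the called genes numbered 149 to 666 in 2023, 162 to 1603 in 2024, 0 to 13 for the difference between years and 64 to 221 in both years. DESeq2 called 835 genes in 2023, among them 460 of the 460 called by edgeR, 17 for the difference and 358 in both years. A fit of all 14 libraries called 723 in 2023, and leaving out green manure libraries 1 and 2 together 788, 337 of them among the 460. The green manure group of that last fit was libraries 3 and 4, the pair with the lowest chi-square of the duplicate check. With no filter on low counts 975 genes were called in 2024 and 4 for the difference. With an absolute log2 fold change of at least 1 they numbered 152 in 2023, 195 in 2024 and 41 in both years. The cause of these moves was not tested, except that the last follows from the stricter threshold. Apart from the replicate block below, other counts moved by less than 1.5 times, and 0 results for named genes reversed. Of 159 calls of named genes 61 were kept with every library left out in turn.

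The treatments share replicate numbers within a year. With the replicate block 1616 genes were called in 2024, 344 in 2023, 186 in both years and 1 for the difference. Correlations of libraries with the same number were -0.12, 0.05, 0.15 and -0.09 in 2023, against at best 0.22, 0.28, 0.15 and 0.19 with another number. In 2024 they were 0.26, 0.2 and 0, against at best -0.13, 0.13 and 0.04. In neither year did every library correlate best with its own number, so the numbers were not taken as pairs. Libraries 1 and 2 of 2024 did, so pairing in that year is not excluded.

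Of 35 splits of the libraries of 2023, 1 (the real one) gave as many as 460 genes, the highest other 52. This share lies under 0.05 but is the smallest that 35 splits can give. Splits that mix the treatments also put the treatment effect into the spread within groups, which lowers their counts. Chance is therefore not excluded. Of 10 splits for 2024, 1 gave 626 and the highest other 0, and 10 splits are too few for a share under 0.05. Of 100 splits for both years, 1 gave as many as 166 and the highest other 0. Every split of 2024 but the real one called 0 genes, so a split that mixes 2024 could share 0 genes only. The splits of single years thus largely fixed this outcome, and chance is not excluded.

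For lists, camera called 6 in 2023 and 13 in 2024, also with DESeq2 size factors, 5 and 12 with the replicate block, and 0 and 0 with an estimated correlation (lowest adjusted p 0.367 and 0.249). The directional fry test called 1 (cytokinin) and 2 (defence and terpene synthases), and the mixed test 13 and 11. For the difference between years the directional test called 1 list, defence, and the mixed test 2. In simulated data 43% of 2-fold differences between years were recovered, which limits the count of genes called for the difference more than the other counts.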

Other observations

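The genes of the first paragraph, the gene ontology test, the superoxide dismutase and copper loci and 2 of the tests below (clock genes, and other superoxide dismutases) were chosen only after results were seen.

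Several single genes of nitrogen metabolism passed the test in both years, though they were picked by their values and the fixed nitrogen list was not called in 2023 (camera adjusted p = 0.312). DUR3 (Os10g0580400), a urea transporter, fell from 87 ± 17.5 to 50 ± 3.22 CPM in 2023 (-0.80 ± 0.13, n = 4) and also in 2024 (-1.21 ± 0.21, n = 3). ALN (-0.77 ± 0.14 and -1.85 ± 0.19), PRODH (-0.85 ± 0.12 and -1.98 ± 0.24) and NRT2.4 (-0.45 ± 0.11 and -1.60 ± 0.16) fell in 2023 and 2024. The call of NRT2.4 in 2023 was lost in 7 of 8 fits without a library (adjusted p up to 0.191) and that of DUR3 in 2024 in 3 of 6 (up to 0.0921), both by edgeR. The threonine synthase gene Os01g0693800 (0.83 ± 0.12 and 1.29 ± 0.16) rose, as did the serine acetyltransferases SAT2;2 (Os03g0196600, 1.41 ± 0.30 and 1.13 ± 0.19) and SAT3 (Os03g0133900, 0.49 ± 0.12 and 0.62 ± 0.11), whose enzymes start cysteine synthesis. The calls of SAT2;2 and SAT3 were lost in 5 and 7 of 8 such fits in 2023 (up to 0.143 and 0.166) and in 2 and 3 of 6 in 2024 (up to 0.083 and 0.0818). Among 347 gene ontology terms, light harvesting in photosynthesis held 4 of the genes higher in both years (CAB2R, CP26, LHCA2 and LHCB2.1, 0.11 expected, hypergeometric test, adjusted p = 0.00118). CAB2R, CP26 and LHCB2.1 are also in the light-harvesting list, so this is not separate evidence. The hypergeometric test treats genes as independent, and genes of one term can move together. Polysaccharide binding held 5 of the genes lower in both years (WAK14, WAK45, WAK82, WAK85 and Os11g0691400, 0.182 expected, adjusted p = 0.000316). Amino acid biosynthesis, amino acid metabolism and cysteine biosynthesis from serine were not called for the genes higher in both years (adjusted p = 0.141 for each).

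Of 20 tested light-harvesting genes 7 were called higher by edgeR in each year and 13 were not, with a median of 0.67 in each and a camera call that was lost in both (adjusted p = 0.696 and adjusted p = 0.468 with an estimated correlation). Leaves picked at another time of day would move clock genes as well, but the median absolute change of 12 clock genes was 0.14 in 2023 and 0.12 in 2024, with 0 called by edgeR or DESeq2 and 1 in each year at an unadjusted p under 0.05. The lowest median of the light-harvesting list over 3 scalings and both years was 0.43, which argues against scaling as the whole cause. Without green manure libraries 1 and 2 of 2023 its median was 0.61. That value rests on green manure libraries 3 and 4, the pair with the lowest chi-square of the duplicate check. Differences between fields or plots stay open, because the labels do not say how many stood behind the leaves. Other tissue in the leaf samples also stays open. Its markers OsLsi1 (0.89 ± 0.22 and 0.39 ± 0.13) and OsCDKB2;1 (1.58 ± 0.57 in 2024) were higher with green manure, though not called by edgeR. Tissue low in light-harvesting transcripts would have to be more abundant with chemical fertilizer to explain the rise. These few markers give no backing to that explanation and cannot decide it.

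Of 5 genes with a Cu/Zn superoxide dismutase domain, 1 was lower with green manure in 2023 and 4 in 2024 (medians -0.87 and -1.03). SODCC1 (Os03g0351500) had -0.72 ± 0.22 and -1.03 ± 0.11, SODCC2 (Os07g0665200) -1.02 ± 0.33 and -1.43 ± 0.10, and the chaperone gene SOD (Os04g0573200) -0.87 ± 0.21 and -1.03 ± 0.11, of which the values of 2024 passed the test. SOD2 (Os03g0219200) had 0.23 ± 0.16 and 0.11 ± 0.11. Of the COPT copper transporters 1 of 3 tested was higher in 2023 and 2 of 5 in 2024, and 0 were lower. COPT1 (Os01g0770700) rose in both years (1.30 ± 0.15 and 1.24 ± 0.12). Not called were COPT4 (Os04g0415600, 0.18 ± 0.16 and -0.28 ± 0.15), COPT7 (Os09g0440700, 0.31 ± 0.15 and 0.18 ± 0.13) and COPT3 (Os03g0370800, -0.09 ± 0.49 in 2024). COPT6 (Os08g0455900) rose in 2024 (3.60 ± 0.69) on few reads, 2, 2 and 0 with chemical fertilizer and 15, 15 and 11 with green manure, and its call was lost in 4 of 6 fits without a library (adjusted p up to 0.0776 by edgeR). In 2023 the filter on low counts left it untested, with 1, 0, 0 and 1 reads with chemical fertilizer and 51, 33, 9 and 23 with green manure.

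The superoxide dismutases with manganese or iron had medians of 0.09 and -0.11, which argues against a fall of all superoxide dismutases, although SODA1 (Os05g0323900) had -0.42 ± 0.12 (adjusted p = 0.0722 by edgeR) in 2024. A candidate explanation, stated as a hypothesis, is a copper-saving response, in which MIR408 rises and some other copper proteins fall. It required laccase genes and named targets of the microRNA to fall, but 1 and 3 of 24 loci were tested. All of them were laccases and 0 were of the 2 named targets. Their medians were 1.59 and 0.30, with 0 called by edgeR. PC, a copper protein outside this condition, had 0.33 ± 0.16 and 0.37 ± 0.16 and is not counted for or against the hypothesis. The condition written beforehand against the hypothesis, a median of 0 or above in either year, was met, but on few loci. In 2023 it rested on LAC8 alone (1.59 ± 0.77, adjusted p = 0.375 by edgeR). A minimum of 3 loci was added after the condition was written. These loci give no backing to the hypothesis and cannot decide it.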
